A study of Homo sapiens with 8 samples.

How the data were processed

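The 8 libraries were total RNA of DU145 and PC3, human prostate cancer cell lines, each transfected with a plasmid carrying circ0003553 or circ0004592, circular RNAs (circRNAs), or with the negative control plasmid of the same arm. Ribosomal RNA was removed, stranded libraries were made with a kit that adds an 8-base molecular identifier, and the libraries were sequenced in pairs of 150 bases on a NovaSeq. The titles give the line and the arm but no replicate number. DU145 was numbered replicate 1 of every group and PC3 replicate 2, so each line holds 1 library per group.

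The authors trimmed the reads with Trimmomatic 0.36, counted them per gene with featureCounts from Subread 1.5.1 on hg38 and used edgeR 3.12.1. The deposited tables give raw read counts per gene and, apart from these, RPKM per gene, with 1 pair of tables per arm. The aligner, the annotation release, the strand setting and the use of the molecular identifiers are not given, so a pair of overlapping genes on opposite strands may share counts. The tables list 36779 genes, of which 31268 stand in both tables of counts. The 5511 genes listed in just 1 of these had at most 14 counts there and were given 0 in the other.

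All comparisons started from the counts. Genes with at least 1 CPM (counts scaled to the library's effective size) in at least 2 libraries were tested, 17877 in all, with TMM factors and the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with limma 3.58.1 and version 1.17.8 of data.table. An adjusted p is the Benjamini-Hochberg value over the tested genes and the threshold was 0.05. An SE given with an edgeR value is the absolute log2 change divided by the square root of its F statistic. It was worked back from the test and can be too small for genes with few counts. For each circRNA, and for the difference between them, all 8 libraries were fitted with a block for each line and arm (4 blocks, 2 residual degrees of freedom), so each circRNA library was set against the control of its own line and arm. The lines were compared with a block per group (3 residual degrees of freedom). For the interaction of line and circRNA, the 6 groups of line and treatment were fitted, with the controls of a line as 1 group. This leaves 2 residual degrees of freedom, and each lone circRNA library was assumed to vary like the controls.

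The design, the comparisons, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Tests within each line were added after the data were seen. They came from the fit of 6 groups, against both controls of the line, and from a fit of 4 groups that sets both circRNA libraries of a line against both controls (4 residual degrees of freedom). Fold changes within a line against the own control used a prior count of 2 and carry no test. The correlations of these folds between the circRNAs were also added.

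Of 45 gene lists, the 43 with at least 5 tested members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. The estimated correlation and its test rest on 2 residual degrees of freedom, or 3 for the lines. Few lists could pass there whatever their change, so failing it does not show that a list is unchanged. Within a line, the median of a list was placed among 10000 random lists of equal size. The leukocyte and erythroid lists were read as CPM only. Even numbers made up 64.9% to 66.1% of the counts from 1 to 20 in a library, as when both reads of a pair are counted. The read pair was therefore taken as the unit of counting error, a choice made after the data were seen. A gene with 0 counts in a library was given a bound of 3 read pairs, or 6 counts, in that library. Intervals of RCAN3 and STK3 are 95% Clopper-Pearson intervals of the counts divided by 2, carried over to the ratio, and intervals and floors cover counting error only.

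Genes were named by a rule. For each circRNA these were the 10 largest rises and falls past the threshold with the same sign in both lines, and where too few passed, places were filled with genes of at least 5 CPM and the same sign, ranked by the smaller of the within-line folds and given as values only. Also named were the 5 largest rises and falls within each line at 5 CPM or more in 1 of 2 libraries, and the 5 smallest p-values of the difference and of each interaction. For the lines they were the 10 largest changes per direction at a mean of 20 CPM or more. List members past the threshold were named up to 4 per list in order of absolute fold, and RCAN3 and STK3 were named in any case. Genes without a symbol, XIST and Y-linked genes were left out, and a few genes that the rule names are not printed. Positions are from the deposited tables, in hg38.

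The alternatives were DESeq2 size factors, DESeq2 1.42.0 as the tool, no filter, filters of 5 and 20 CPM, a prior count of 10, pooled controls, the libraries of 1 arm alone, no block, RPKM (log2 after adding 0.1) with limma, and each replicate left out. The fit with no block drops the cell line, since the replicate numbers are the cell lines. With no block, edgeR called 0 genes for each circRNA and for their difference, as with the block. The difference between the lines then enters the spread and few calls could arise, so this does not check the pairing. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

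The comparisons were tested on simulated data. Counts were drawn from the mean profiles of the controls with the spread of each fit, and known changes were put in genes at a mean of 5 CPM or more. For each circRNA and for their difference, a change had the same size in both lines. A lone circRNA library was drawn with the same spread as the controls. The simulation therefore cannot check whether it varies like them. With a 2-fold change, edgeR recovered 49.3% of the changed genes for circ0003553, 58.2% for circ0004592, 14.9% for their difference, 98.5% for the lines and 92.5% for the interaction of circ0003553. Of 17677 unchanged genes, at most 12 were called in any comparison simulated. All 4-fold changes were recovered for both circRNAs, and 90.9% for the difference. Changes that differ between the lines were not simulated for these, so 0 calls over both lines do not rule out large changes in 1 line. Within DU145 and PC3, 98.5% and 97.0% of the 2-fold changes of circ0003553 were recovered. A raised interferon list was called and 0 other lists were. Genes were drawn independently there, with the spread of the fit of 6 groups. False calls of lists with correlated genes were therefore not checked. In the real data, the interferon list had an estimated correlation of 0.883 with circ0003553. The residuals of that fit hold the difference between the lines in the effect of a circRNA.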

Results

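RNA of 8 libraries was compared, 1 each of DU145 and PC3 for circ0003553, its control plasmid, circ0004592 and its control plasmid. The titles carry the gene names RCAN3 for the circ0003553 arm and STK3 for the circ0004592 arm. In DU145, total counts were 45210390 in the circ0003553 control, 49926342 with circ0003553, 38134966 in the circ0004592 control and 33739149 with circ0004592. In PC3 they were 35512031, 33608681, 35446337 and 33444940 in the same order. The floor of 3 read pairs (6 counts) lay between 0.120 and 0.179 CPM. Gene counts of all tested genes correlated across genes at r = 0.995 between the DU145 controls and 0.994 between the PC3 controls. No group had replicates within a line, and nothing in the labels says whether the arms were separate cultures.

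circ0003553 came with a large rise of interferon-stimulated genes in PC3 and a small rise of some of them in DU145. MX1, a GTPase that blocks virus replication, went from 23.4 to 2673 CPM in PC3 and from 34.8 to 41.1 CPM in DU145. PC3 also had more messenger RNA of some cytokine and apoptosis genes, such as IL6 and PMAIP1, and less of mitochondrial and ribosomal protein genes. In DU145, MMP1 (a collagenase that breaks down matrix) and TXNIP (an inhibitor of thioredoxin) rose, and genes of cholesterol synthesis fell. The comparison asks which messages change when this circRNA is supplied on a plasmid.

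In PC3, 31 of the 32 interferon and antiviral genes rose with circ0003553 (31 adjusted over the list alone). The exception was DHX58, at 0 counts in both libraries. The median fold was 41.7, or 37.8 with the members that had no control counts at their bound. MX1 (chromosome 21, 41420304 to 41459214) rose by 6.82 ± 0.06 (log2, SE; edgeR adjusted p = 5.11e-29). IFIT2 and IFIT3, which bind viral RNA, reached 2916 and 2861 CPM from 34.5 and 47.5 CPM. RSAD2 (viperin), an antiviral enzyme, went from 0.787 to 772 CPM, and OASL, of the oligoadenylate synthetase family, from 1.43 to 570 CPM. CXCL11, a T cell chemokine, had 2 counts in the control and 1718 with circ0003553. XAF1, which promotes apoptosis, had none in the control and 26.4 CPM with circ0003553, at least 156-fold higher. The lncRNA RP11-609D21.3 at the same locus was at least 115-fold higher, and without the strand setting their counts cannot be separated. PLEKHA4, an adaptor that binds phosphoinositides, rose from 9.50 to 218 CPM.

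**Figure D1:**
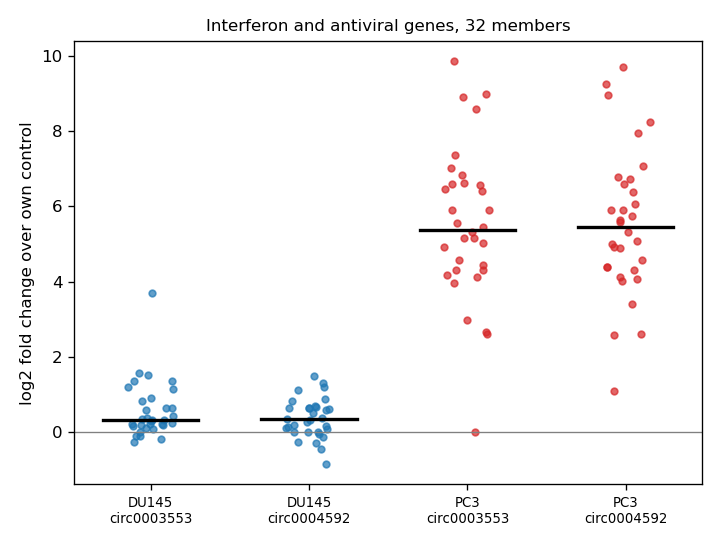
Log2 fold change over the own control of the 32 interferon and antiviral genes, 1 point per gene and 1 column per line and circRNA, with the median as a bar. The medians were 0.33 and 0.35 in DU145 and 5.38 and 5.45 in PC3.

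Other groups moved in PC3 with circ0003553. Of 22 cytokine and NF-kB genes, 13 rose and 2 fell (16 past the threshold adjusted over the list alone), with IL6 at a log2 fold of 2.69, the prostaglandin synthase PTGS2 at 1.55 and the apoptosis inhibitor BIRC3 at 1.53, while the chemokine CXCL5 fell (-1.43). Of 24 apoptosis regulators, 10 rose, 1 fell and 13 did not pass (12 adjusted over the list alone), and PMAIP1 (NOXA, a BH3-only protein) had 2.46 and CASP8 1.07. All 13 mitochondrially encoded messages fell (13 adjusted over the list alone), by a median log2 of -0.79, with cytochrome b (MT-CYB) at -1.01. Of 39 cytosolic ribosomal proteins, 38 fell (38 adjusted over the list alone), by a median of -0.36, among them RPL3 (-0.73) and RPS6 (-0.60). Of 30 integrated stress response and amino acid genes, 22 fell and 2 rose (24 adjusted over the list alone), with the pseudokinase TRIB3 at -0.93 and cystathionine gamma-lyase (CTH) at -0.83, while the tryptophanyl-tRNA synthetase WARS rose (0.84). Of 25 YAP and TEAD targets, 14 rose and 3 fell (19 adjusted over the list alone), including the actin binder LIMA1 (0.97) and the matricellular protein gene CTGF (0.76). MAPK feedback genes fell in 11 of 21 and rose in 2 (15 adjusted over the list alone), with the EGF family ligands HBEGF (-1.17) and TGFA (-1.07) lower. Single genes that fell were CLN8, a protein of endoplasmic reticulum export (13.5 to 2.93 CPM), the p53 target ZMAT3 (16.4 to 4.14 CPM) and the basal keratin KRT15 (68.0 to 19.4 CPM). These list directions were kept under all 3 scalings tried for mitochondrial, ribosomal protein, interferon, YAP and MAPK genes.

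In DU145 with circ0003553, the 32 interferon genes had a median log2 change of 0.33 over the whole list. Rises and falls counted in this line rest on 1 circRNA library and on the spread of 2 controls. They were not called by limma on RPKM. IFI44, an interferon-induced cytoplasmic protein, went from 3.76 to 9.80 CPM, and IFIT2 from 10.6 to 18.9 CPM. OAS2, an oligoadenylate synthetase, had 0 counts in the control and 32 with circ0003553, at least 4.75-fold higher, and XAF1 rose from 0.176 to 0.608 CPM. Both were under 1 CPM in the control, where counts carried over from PC3 libraries were not excluded. MMP1 rose from 19.9 to 57.1 CPM (log2 1.51 ± 0.09 SE, edgeR adjusted p = 2.46e-10). The pseudogene WTAPP1, beside MMP1, went from 14.4 to 38.2 CPM, and the strand setting is not known. TXNIP rose from 2.42 to 9.92 CPM and the B cell lectin gene CD22 from 2.64 to 8.76 CPM. PLEKHA4, which rose in PC3, fell in DU145 from 25.5 to 11.2 CPM, and the guanylate-binding protein GBP3 fell from 9.29 to 6.23 CPM. All 13 mitochondrially encoded messages rose, by a median log2 of 0.47 (13 adjusted over the list alone). Of 23 cholesterol genes, 13 fell and 0 rose (17 adjusted over the list alone), with lanosterol synthase (LSS) at -0.56 and the mevalonate enzymes MVK and MVD at -0.46 and -0.45. The 25 YAP and TEAD targets had a median log2 change of -0.18, beside 0.43 in PC3, and the 21 MAPK feedback genes had one of 0.15. In PC3, 12 of the 23 cholesterol genes fell and 1 rose, the lipid carrier STARD4 (13 adjusted over the list alone).

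Within PC3, edgeR called 5152 genes for circ0003553 (2564 higher, 2588 lower, 586 and 251 of them by at least 2-fold), DESeq2 2565 (1538 higher, 1027 lower) and limma on RPKM 3305 (1468 higher, 1837 lower). Within DU145 edgeR called 1947 (826 higher, 1121 lower), and 672 without the DU145 circ0003553 control or 759 without the DU145 circ0004592 control. In DU145, DESeq2 called 820 (219 higher, 601 lower) and limma on RPKM 0. These tests were added after the data were seen and take the lone circRNA library to vary like the controls. In DU145, the mean chi-square per gene was 4.89 between the counts of the controls and 30.4 between those of the circRNA libraries. In PC3 it was 4.49 and 8.78. The circRNA libraries carry different inserts, so their spread cannot be separated from their effects, and the assumption was not checked. Over both lines, edgeR called 0 genes (519 at an unadjusted p under 0.05, DESeq2 11 with 4 higher and 7 lower). It called 38 with no filter (37 higher, 1 lower), 25 with pooled controls (23 higher, 2 lower) and 6 without DU145, where 1 circRNA library faces 1 control and the spread is taken from the other arm. The smallest adjusted p of the 0-gene result was 0.0853, for IDO1, an enzyme that breaks down tryptophan (1.07 to 51.7 CPM in PC3, 0 counts in both DU145 libraries). Over both lines, camera called the interferon list (adjusted p = 1.8e-22), NF-kB genes (0.0334), histones (0.0202) and DNA repair (0.0297) as higher. It called cholesterol (2.51e-05), fatty acid synthesis (0.0359), stress response and amino acid genes (0.0334) and cytosolic ribosomal proteins (0.00854) as lower. None of these 8 passed with an estimated correlation (adjusted p = 0.958 for each with an estimated correlation). Few lists could pass that test with 2 residual degrees of freedom. Not all of these lists moved in both lines. In DU145, the median log2 change was 0.01 for NF-kB genes, -0.05 for stress response and amino acid genes and 0.04 for ribosomal proteins. In PC3 these medians were 0.35, -0.28 and -0.36. Among the histones, 6 of 10 rose in PC3 (6 adjusted over the list alone) and 0 in DU145, HIST1H2AE by 1.14 on the log2 scale. The 25 DNA repair genes had a median log2 change of 0.15 in PC3 and 0.10 in DU145. In PC3 the helicase BRIP1 rose by 1.46 and the checkpoint kinase CHEK2 by 0.97. The 16 fatty acid genes had a median log2 change of -0.25 in PC3 and -0.11 in DU145, with the desaturase SCD at -0.57 and -0.38.

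circ0004592 came with the same kind of change in PC3, a rise of interferon-stimulated genes, and with a small rise of some of them in DU145. MX1 went from 23.8 to 2549 CPM in PC3 and from 33.5 to 50.7 CPM in DU145. In PC3, mitochondrial and ribosomal protein messages were lower and some cytokine genes, such as IL6, higher. In DU145, MMP1 and heat shock genes rose, and the sterol sensor INSIG1 fell. The question is the same as for the other circRNA.

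In PC3, 31 of the 32 interferon genes rose with circ0004592 (31 adjusted over the list alone), with DHX58 again at the floor. The median fold was 43.7, or 36.9 with members without control counts at their bound. MX1 rose by 6.75 ± 0.06 (log2, SE; edgeR adjusted p = 6.19e-29). IFIT2 went from 34.1 to 2857 CPM, IFIT3 from 42.8 to 2569, RSAD2 from 1.45 to 750 and OASL from 1.73 to 539. CXCL11 had 0 control counts and was at least 258-fold higher at 43.2 CPM, and XAF1 at least 190-fold higher at 31.8 CPM. BST2 (tetherin), which holds virions at the membrane, went from 2.01 to 503 CPM, and IFITM1, which blocks virus entry, from 1.42 to 101 CPM. PLEKHA4 went from 9.79 to 203 CPM. NF-kB genes rose in 10 of 22, fell in 1 and did not pass in 11 (13 adjusted over the list alone), with IL6 at a log2 fold of 1.82 and PTGS2 at 1.76. All 13 mitochondrially encoded messages fell, by a median log2 of -0.44 (13 adjusted over the list alone), and 33 of 39 ribosomal proteins fell, by a median of -0.38 (36 adjusted over the list alone), with RPS14 at -0.68. YAP and TEAD targets rose in 14 of 25 and fell in 7 (22 adjusted over the list alone), the ectonucleotidase NT5E by 1.12, while TGFB2, a TGF-beta ligand, fell (-1.15). MAPK feedback genes fell in 11 of 21 and rose in 2 (13 adjusted over the list alone), HBEGF at -1.26. ZMAT3 fell from 16.2 to 3.39 CPM, CLN8 from 12.2 to 3.39 CPM and the neurotensin receptor NTSR1 from 59.7 to 28.0 CPM.

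In DU145 with circ0004592, the 32 interferon genes had a median log2 change of 0.35 over the list, and IFI44 went from 4.79 to 7.37 CPM. Rises and falls counted here rest on 1 circRNA library and on the spread of 2 controls. They were not called by limma on RPKM. MMP1 rose from 20.3 to 53.2 CPM (log2 1.41 ± 0.09 SE, edgeR adjusted p = 2.01e-09), TXNIP from 2.59 to 7.55 CPM, NTSR1 from 1.89 to 5.10 CPM and CD22 from 2.83 to 6.88 CPM. PLEKHA4 fell to 10.7 CPM (log2 -1.23) and GBP3 from 10.2 to 4.64 CPM. The 19 heat shock genes had a median log2 change of 0.21, with HSPA1A at 0.77, HSPA1B at 0.73 and the constitutive chaperone HSPA8 at 0.71. HSPA1A and HSPA1B are near-identical paralogs that may share reads. MAPK feedback genes rose in 8 of 21 and fell in 1 (9 adjusted over the list alone), with the ephrin receptor EPHA4 at 1.12 and the phosphatase DUSP4 at 0.67. YAP and TEAD targets fell in 7 of 25 and rose in 2 (11 adjusted over the list alone). Cholesterol genes fell in 7 of 23 and rose in 0 (10 adjusted over the list alone), INSIG1 at -0.82 and the desaturase SC5D at -0.65. Mitochondrially encoded messages rose in 5 of 13 (7 adjusted over the list alone), by a median log2 of 0.06. TGFB2-AS1, antisense to TGFB2, fell in all 4 comparisons within a line, from 31.9 to 17.6 CPM in DU145 and 16.1 to 7.75 CPM in PC3 with circ0004592.

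Within PC3, edgeR called 4597 genes for circ0004592 (2192 higher, 2405 lower, 550 and 228 by at least 2-fold), DESeq2 2266 (1217 higher, 1049 lower) and limma on RPKM 2641 (1232 higher, 1409 lower). Within DU145 edgeR called 1866 (1060 higher, 806 lower), and 864 without the DU145 circ0003553 control or 490 without the DU145 circ0004592 control. In DU145, DESeq2 called 835 (565 higher, 270 lower) and limma on RPKM 0. Over both lines, edgeR called 0 genes (542 at an unadjusted p under 0.05, DESeq2 13 with 5 higher and 8 lower). It called 36 with no filter (34 higher, 2 lower), 32 with pooled controls (27 higher, 5 lower) and 2 without DU145, with the spread again from the other arm. The smallest adjusted p of the 0-gene result was 0.0873, for IDO1 (1.12 to 49.9 CPM in PC3). Over both lines, camera called the interferon list (adjusted p = 1.17e-20), NF-kB genes (0.0135) and histones (0.0135) as higher, and cholesterol (0.0135) and fatty acid synthesis (0.0135) as lower. None of these 5 passed with an estimated correlation (adjusted p = 0.853 for each with an estimated correlation), which few lists could pass with 2 residual degrees of freedom. The NF-kB genes had a median log2 change of 0.07 in DU145 and 0.27 in PC3. Histones rose in 4 of 10 in PC3 (5 adjusted over the list alone) and in 0 in DU145, HIST2H2BE by 1.66 on the log2 scale in PC3. The 16 fatty acid genes had a median log2 change of -0.26 in PC3 and -0.10 in DU145, with SCD at -0.48 and -0.49.

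The change with each circRNA differed between the lines, most of all in interferon-stimulated genes. Each circRNA is 1 library per line, and the SE and p rest on the spread of the 2 controls of each line, which may not be separate cultures. MX1 rose more in PC3 than in DU145 by 6.55 ± 0.09 (log2, SE; edgeR adjusted p = 1.55e-24) with circ0003553 and by 6.18 ± 0.09 (6.06e-24) with circ0004592. IFIT3 differed by 5.61 and 5.49, IFIT2 by 5.63 and 5.95 and OAS3 by 5.09 and 4.88. PLEKHA4 went in opposite directions, higher in PC3 and lower in DU145, and differed by 5.67 and 5.63. MMP1 went the other way, higher in DU145 and lower in PC3 (2.92 to 1.33 CPM and 2.70 to 1.26 CPM), and differed by -2.58 and -2.56.

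By edgeR, 4047 genes differed between the lines in the effect of circ0003553 (2170 higher in PC3, 1877 lower), and 3621 for circ0004592 (1751 higher, 1870 lower). DESeq2 gave 2016 (1355 higher, 661 lower) and 1807 (915 higher, 892 lower). Camera called 12 lists for each circRNA at the preset correlation and 0 with an estimated correlation, where the adjusted p of the interferon list was 0.35 for circ0003553 and 0.299 for circ0004592. With 2 residual degrees of freedom few lists could pass the latter test, so its 0 calls do not decide whether the lists differed. At the preset correlation with circ0003553, the interferon list differed (camera adjusted p = 6.59e-57), as did mitochondrially encoded messages (5.85e-25), cytosolic ribosomal proteins (1.17e-18), YAP and TEAD targets (1.62e-09) and MAPK feedback genes (5.74e-06). With circ0004592 these were 1.96e-62, 5.63e-12, 2.45e-17, 1.82e-05 and 4.19e-06. Members higher in PC3 with circ0003553 were 30 of 32 interferon genes and 17 of 25 YAP and TEAD targets. Members lower were 13 of 13 mitochondrial messages, 34 of 39 ribosomal proteins and 13 of 21 MAPK feedback genes.

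**Figure D2:**
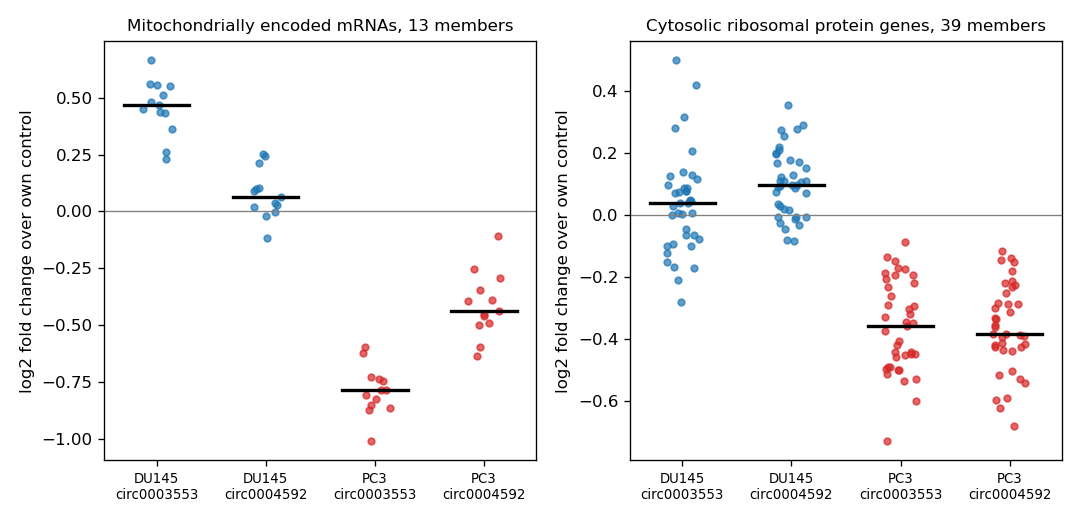
Log2 fold change over the own control of the mitochondrially encoded messages and the cytosolic ribosomal proteins, 1 point per gene, by line and circRNA, with the median as a bar. The mitochondrial medians were 0.47 and 0.06 in DU145 and -0.79 and -0.44 in PC3, and the ribosomal protein medians were 0.04 and 0.10 in DU145 and -0.36 and -0.38 in PC3.

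Fold changes of the circRNAs went together in PC3, where interferon genes such as MX1 and RSAD2 led both, and less so in DU145. Across the tested genes, log2 folds of circ0003553 and circ0004592, each against its own control, correlated at r = 0.762 in PC3 (rho 0.606), with the same sign in 74.1% of genes. Without the interferon list and the genes changed over 4-fold in PC3, r was 0.570. In DU145, r was 0.142 between the circRNAs. Between the lines, r was 0.056 for circ0003553 and 0.027 for circ0004592. Genes are not independent replicates, and these r carry no test.

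For the difference between the circRNAs, edgeR called 0 genes (50 at an unadjusted p under 0.05, DESeq2 0) and camera called 0 lists. The smallest p was that of RMI1, a subunit of the complex that dissolves recombination intermediates, at a log2 difference of 1.01 ± 0.26 (SE; edgeR adjusted p = 1). In the data simulated with 2-fold differences of the same size in both lines, 14.9% were recovered.

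**Figure D3:**
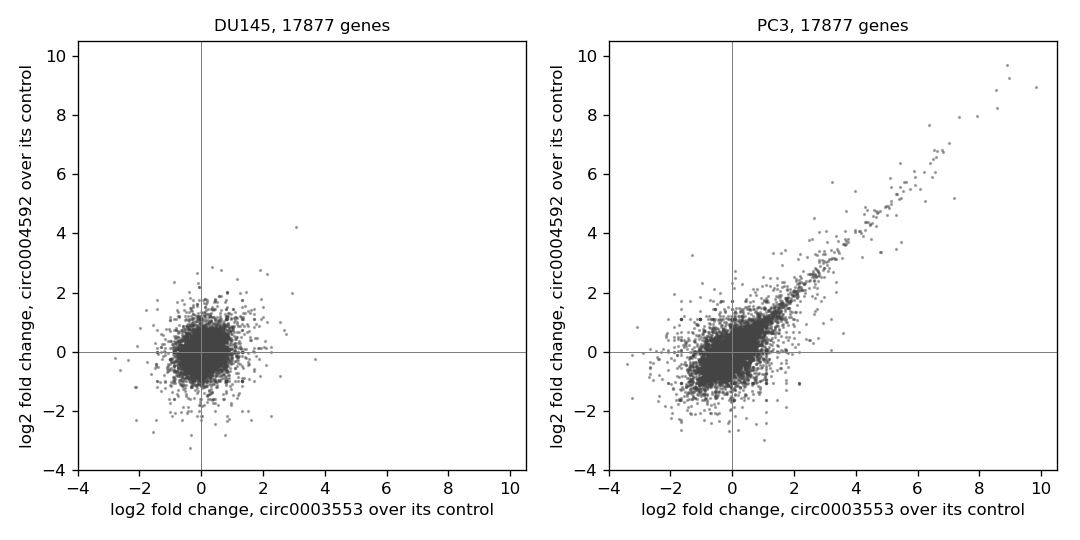
Log2 fold change of each tested gene with circ0004592 against that with circ0003553, each over its own control, in DU145 and in PC3. In PC3 the genes spread along the diagonal (r = 0.762), and in DU145 they did so less (r = 0.142).

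DU145 and PC3 differed in most genes, among them genes of epithelial and mesenchymal cells. CDH2 (N-cadherin, of mesenchymal junctions) had 0 counts in the DU145 controls and 51.0 CPM in PC3, while CDH1 (E-cadherin, of epithelial junctions) was lower in PC3 by -5.74 on the log2 scale. PC3 expressed the prostate homeobox gene HOXB13 (265 CPM against 0.0393), the cytokine gene IL1B (405 against 0.0744) and the collagen gene COL6A3 (759 against 0.0482). DU145 expressed the ubiquitin hydrolase UCHL1 (412 against 0.0562 CPM) and the caveolar coat gene PTRF (1122 against 0.406). CPM here are means of the 2 controls of a line.

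By edgeR, 13735 genes differed between the lines (6875 higher in PC3 and 6860 lower, 3648 and 3564 by at least 2-fold). The smallest adjusted p was that of EPB41L3, a membrane skeleton protein, higher in PC3 by 12.54 (log2; edgeR adjusted p = 4.83e-08). It had 2 counts in each DU145 library, so the size of this fold is uncertain. None of the 8 lists called here passed with an estimated correlation, whose adjusted p follows that of the preset one. Few lists could pass it with 3 residual degrees of freedom. Of 27 epithelial genes, 21 were lower in PC3 and 2 higher (camera adjusted p = 4.95e-06, 0.456 with an estimated correlation), with the protease ST14 at -6.66 and the claudin CLDN1 at -5.32. Of 25 mesenchymal genes, 13 were higher, 7 lower and 5 not past (6.51e-05, 0.528). TWIST1 and SPARC had 0 counts in all 4 DU145 libraries and means of 13.8 and 2.26 CPM over the 4 PC3 libraries, while TGFBI was lower in PC3 (0.143 against 52.4 CPM, over 4 libraries each). S phase genes were lower in 31 of 33 (2.16e-08, 0.528), with the replication factor MCM10 at -3.44, and mitosis genes in 31 of 34 (1.15e-05, 0.55), with the kinesin KIF20A at -2.51. NRF2 targets were lower in 19 of 23 (0.000126, 0.456), with NQO1 at -3.04. YAP and TEAD targets were lower in 19 of 25 (0.00356, 0.739), with ANKRD1 at -3.73. DNA repair genes were lower in 19 of 25 (0.00156, 0.528), and endothelial genes were higher in 5 of 6 (0.00181, 0.528), with KDR at means of 43.1 CPM in PC3 and 0.0820 CPM in DU145 over 4 libraries each.

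RCAN3, an inhibitor of calcineurin, and STK3, the MST2 kinase of the Hippo pathway, are the gene names in the titles of the circ0003553 and circ0004592 arms. Gene counts of RCAN3 were higher with circ0003553 in both lines, and those of STK3 were higher with circ0004592 in both. The tables hold no identifier of either circRNA, so these are counts of the genes and no value of the circRNAs is given. Whether reads of the supplied circRNAs were counted within these genes is not known. The rises below therefore may be of the plasmid insert, of the gene's own RNA or of both. STK3 is also a member of the Hippo list. Ratios and intervals below are against the own control, while the adjusted p within a line is from the fit against both controls of the line. With circ0003553, RCAN3 went from 949 to 1893 counts in DU145, a CPM ratio of 1.78 (95% interval 1.59 to 1.99; edgeR adjusted p = 9.64e-07 within the line). In PC3 it went from 1180 to 1455, a ratio of 1.33 (1.19 to 1.48; adjusted p = 0.000313). With circ0004592, STK3 went from 327 to 641 counts in PC3, a ratio of 2.11 (1.74 to 2.57; adjusted p = 2.74e-08), and from 998 to 1110 in DU145, a ratio of 1.30 (1.15 to 1.47), which missed the threshold (0.0551). RCAN3 with circ0004592 had a ratio of 0.792 in PC3 (0.693 to 0.904; adjusted p = 0.00316). Over both lines, neither passed: RCAN3 with circ0003553 had a log2 change of 0.62 ± 0.17 (SE; edgeR adjusted p = 0.973) and STK3 with circ0004592 0.72 ± 0.21 (0.985). Of 26 Hippo pathway genes in PC3 with circ0003553, 8 rose and 3 fell (12 past the threshold adjusted over the list alone), the scaffold SAV1 by 0.91 on the log2 scale, while in DU145 0 rose and 5 fell (7). With circ0004592, 8 rose and 2 fell in PC3 (12 adjusted over the list alone), and 1 rose and 2 fell in DU145 (4).

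**Figure D4:**
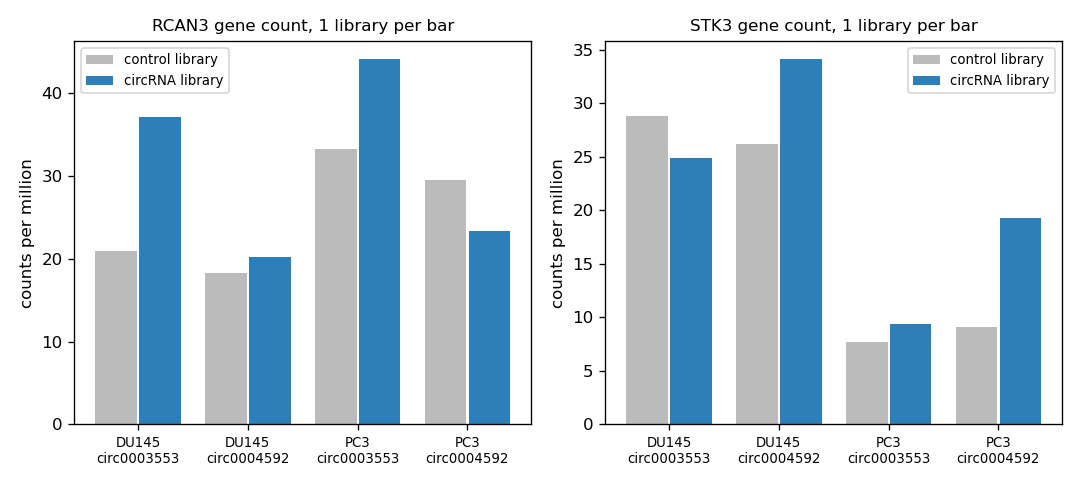
Normalised counts (CPM) of RCAN3 and STK3 in each library, by line and arm, with 1 library per bar and no error bars since there is no replicate within a line. RCAN3 was highest in the circ0003553 libraries of each line, and STK3 in the circ0004592 library of each line.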

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

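In this part, the tests of the interactions and the splits of the libraries were planned, and all the other tests (of leukocytes, scaling, carry-over, shared preparation and ribosomal RNA) were chosen after the result was seen.

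The effect of a circRNA differed between the lines by the interaction test of edgeR in 4047 genes for circ0003553 and 3621 for circ0004592. The values that follow are PC3 minus DU145 on the log2 scale. For genes and lists they come from the fit against both controls of a line, and for lists they are the median over the members. All lists given passed camera at the preset correlation and none with an estimated one.

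For circ0003553 the lists higher in PC3 were interferon genes at 4.85, NF-kB genes at 0.36, S phase at 0.11, mitosis at 0.15, apoptosis regulators at 0.20, Hippo components at 0.23, YAP and TEAD targets at 0.59 and ribosome biogenesis at 0.20. Lower were stress response and amino acid genes at -0.20, cytosolic ribosomal proteins at -0.44, MAPK feedback genes at -0.46 and mitochondrially encoded messages at -1.17. For circ0004592 the lists higher in PC3 were interferon genes at 5.23, mitosis at 0.19, histones at 0.42, apoptosis regulators at 0.10, YAP and TEAD targets at 0.46 and DNA repair at 0.19. Lower were matrix degradation at -0.24, basal keratinocyte markers at -0.52, heat shock at -0.29, cytosolic ribosomal proteins at -0.44, MAPK feedback genes at -0.60 and mitochondrially encoded messages at -0.60.

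Among genes named for circ0003553, those of antiviral defence were higher in PC3: MX1 by 6.55, MX2 by 5.42, IFIT2 by 5.63, IFIT3 by 5.61, OAS1 by 5.61, OAS2 by 3.13, OAS3 by 5.09, OASL by 7.95, RSAD2 by 7.97, IFI44 by 3.90, XAF1 by 11.23, the chemokine CXCL11 by 7.83 and the death ligand TNFSF10 by 5.47. PLEKHA4 was higher by 5.67, CCDC85B by 0.55, RP1-71H24.1 (at the OAS locus) by 4.93 and RP11-609D21.3 (at the XAF1 locus) by 10.79. Lower were MMP1 at -2.58, WTAPP1 beside it at -2.20, TXNIP at -2.08, CD22 at -2.29, RP11-311C24.1 at -1.99, CLN8 at -2.05, CTB-107G13.1 at -3.64, FAM131B at -3.68, ZMAT3 at -2.14, KRT15 at -1.96 and the gene count of RCAN3 at -0.43.

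For circ0004592, MX1 was higher by 6.18, IFIT2 by 5.95, IFIT3 by 5.49, OAS3 by 4.88, OASL by 7.75, RSAD2 by 7.17, IFI44L by 3.30, BST2 by 6.72, IFITM1 by 4.75, CXCL11 by 9.18, XAF1 by 13.78 and RP11-609D21.3 by 13.08. GBP3 was higher by 3.80, PLEKHA4 by 5.63, TMEM27 by 3.09, the ubiquitin-like activating enzyme UBA7 by 1.79, SLC25A27 by 0.83 and the gene count of STK3 by 0.89. Lower were MMP1 at -2.56, WTAPP1 at -2.68, NTSR1 at -2.43, TXNIP at -1.80, TGFB2 at -0.53, MYH16 at -1.36, GS1-358P8.4 at -2.15, ZMAT3 at -2.38, CLN8 at -2.03 and the gene count of RCAN3 at -0.46. Fitted values of genes at or near 0 counts in 1 of the lines (XAF1, RP11-609D21.3, CXCL11, RSAD2, CTB-107G13.1 and FAM131B among them) depend on the prior and are no bounds.

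Interferon genes rose in PC3 with both circRNAs. Leukocytes in the circRNA cultures are argued against by a median of 0.0300 CPM at most over the leukocyte markers there, though CD68, which both lines express, went from 296 to 594 and from 270 to 617 CPM. Scaling between libraries is argued against by a median log2 rise of the list of 5.36 at least under 3 scalings. The circRNA libraries may share a culture, transfection or plasmid preparation that the controls do not, and this cannot be told apart from the inserts, since the folds of the circRNAs went together (r = 0.762 across genes) and no library carries another insert. A response of PC3 to the supplied RNA stays open as a hypothesis, as does a difference between the lines in sensing it, and neither was tested.

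Some interferon genes also rose a little in DU145 by edgeR (17 of 32 with circ0003553 and 10 of 32 with circ0004592, while limma on RPKM called 0 genes there), and PC3 reads carried over into the DU145 libraries may be the source. A first bound on carry-over was the upper quartile of the share found for genes particular to PC3 (0.883% and 0.833%). It exceeded the rises. Their median was 0.552 and 0.548 of the bound with circ0003553 and circ0004592 for members at 1 CPM or more in DU145 controls. For those under 1 CPM the median was 0.0628 and 0.0215 of the bound. By this bound alone, carry-over was not excluded for either class. The bound was replaced after that result was seen by the pooled share of the 10 genes most particular to PC3 (0.0442% and 0.0413%), because carry-over gives every gene 1 share and DU145 may itself express some of the genes first used. By the replacement the rise was 10.6 and 8.87 times the share for members at 1 CPM or more, which argues against carry-over there, and 1.28 and 0.868 times for the others, where carry-over and a rise in DU145 cannot be told apart. For members at 1 CPM or more, the rise in DU145 over that in PC3 had a lower quartile of 0.290% and 0.118%. For members under 1 CPM its median was 0.0566% and 0.0358%, while carry-over would give both classes 1 share. These values argue against carry-over as the only source for members at 1 CPM or more. As the second bound was chosen after the first, it is weaker evidence. For members under 1 CPM, carry-over stays open beside a response of DU145.

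Mitochondrially encoded messages fell in PC3 with both circRNAs and rose in DU145 with circ0003553. Scaling is argued against, as the PC3 median nearest to 0 was -0.43 over 3 scalings. A loss that acts on all mitochondrial RNA, or uneven removal of ribosomal RNA, cannot be told apart from a change of the messages: in PC3 the mitochondrial ribosomal RNAs, which the kit removes to an unknown degree, changed by -0.23 with circ0003553 and 0.02 with circ0004592, and in DU145 by -0.12 and 0.23. With circ0003553 in DU145 they thus moved against the messages (0.47), which a single factor on all mitochondrial RNA would not give, but uneven removal of ribosomal RNA may hide such a factor. Neither RNA quality nor the culture was recorded in the labels, so these may also differ.

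The difference between the lines without a block gave 14141 genes, and 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave as many. The highest of the other splits gave 0 genes. Each of these puts both lines on each side, so the difference between the lines enters the spread. Few calls could arise there whatever the grouping, and the splits therefore do not decide this question.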

How the results depend on the processing

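Most other settings were chosen in advance. Chosen after seeing the data were all alternatives of the tests within a line and of both circRNA libraries together, those of the correlations within a line and of single genes within a line, and the RPKM and left-out controls of the interactions. Where a cause is not given, the cause was not tested.

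For genes called over both lines (0 for each circRNA), DESeq2 gave 11 (4 higher, 7 lower) for circ0003553 and 13 (5, 8) for circ0004592, no filter 38 (37, 1) and 36 (34, 2), pooled controls 25 (23, 2) and 32 (27, 5) and the libraries of 1 arm alone 3 and 3. Leaving out a replicate, which is a cell line, gave 0 to 6 for circ0003553 and 0 to 2 for circ0004592, the higher values without DU145. An arm then holds 1 circRNA library and 1 control, and its spread is assumed to be that of the other arm. DESeq2 factors, a 5 CPM filter, no block and RPKM gave 0. The difference between the circRNAs gave 0 under each alternative run, and leaving out a replicate could not be fitted for it.

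The lines differed in 10509 to 15987 genes under the other settings and in 12712 to 13123 without 1 library. With no replicate block the count was 14141 beside 13735. For the circRNAs and their difference it was 0, but there the difference between the lines enters the spread and few calls could arise. The SE of STK3 with circ0004592 was 0.882 with no block, beside 0.214 with it.

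The interaction counts (4047 and 3621) were 2016 and 1807 by DESeq2 and 1961 and 1619 with RPKM and limma. Without 1 control they ranged from 2955 to 4274 and from 2579 to 3818.

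Within a line, DESeq2 gave 820 and 835 genes in DU145 and 2565 and 2266 in PC3, for circ0003553 and circ0004592. RPKM with limma gave 0 and 0 in DU145 and 3305 and 2641 in PC3. Without 1 control, DU145 gave 672 to 2699 for circ0003553 and 490 to 2529 for circ0004592. PC3 gave 4600 to 4770 and 4032 to 4284.

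With both circRNA libraries of a line against both controls, edgeR called 180 genes in DU145, 3693 in PC3 and 2165 for their difference. In DU145, DESeq2 gave 282, no filter 377 and RPKM with limma 8. Without 1 library DU145 gave 8 (without either DU145 control) to 1436 (without its circ0004592 library), 1263 without its circ0003553 library, 103 without either PC3 control and 99 without either PC3 circRNA library. PC3 gave 1936 without its circ0003553 library, 2245 without its circ0004592 library, 2065 and 2037 without its circ0003553 and circ0004592 controls, and 5748 and 5624 without the DU145 circ0003553 and circ0004592 libraries. The difference gave 1267 without the PC3 circ0003553 library, 1284 and 1295 without the DU145 circ0003553 and circ0004592 controls, 1357 and 1336 without those of PC3, and 3654 and 3876 without the DU145 circ0003553 and circ0004592 libraries.

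With an estimated correlation, camera called 0 lists for circ0003553 (8 with the preset one), circ0004592 (5), the lines (8) and each interaction (12 and 12). That test rests on 2 or 3 residual degrees of freedom, where few lists could pass whatever their change. With pooled controls and the preset correlation, camera called 10 for circ0004592. Without a replicate it called 4 (without PC3) to 11 (without DU145) for circ0003553, and 3 to 3 for circ0004592.

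Correlations moved with the filter. Between the circRNAs in PC3, r was 0.899 at 5 CPM, 0.951 at 20 CPM, 0.837 with a prior count of 10 and 0.570 without interferon and strongly changed genes. In DU145, r was 0.170 and 0.171 at 5 and 20 CPM. Between the lines with circ0003553 it was 0.0852 and 0.135. The filters leave out the genes with fewer counts.

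The log2 change of STK3 with circ0003553 changed sign with pooled controls (-0.0081), with no replicate block (-0.090) and without replicate 2 (-0.21, beside 0.32 without replicate 1), and that of RCAN3 with circ0004592 without replicate 2 (0.14, beside -0.31 without replicate 1). Neither passed a threshold over both lines. Among other values of single genes, 897 stayed the same, 43 became significant in the same direction and 17 moved. For tested values, the same means that direction and threshold were kept. Folds within a line carry no test. For these, the same means a shift smaller than the SE of the fit of 6 groups, and moved means a shift of at least that SE.

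Depth limits genes near the floor of 0.120 to 0.179 CPM, such as CXCL10, at 0 counts in the controls and both DU145 circRNA libraries.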

Other observations

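The hypothesis weighed for leukocytes was chosen after the result was seen, and the values here carry no test. Of 18 leukocyte markers listed, 15 stand in the tables and 1 to 2 reached 1 CPM in a library. The highest was CD68, a lysosomal glycoprotein that both lines express, at 296 and 594 CPM in PC3 (control and circ0003553) and 270 and 617 CPM (control and circ0004592), and at 100 and 126 CPM and 109 and 169 CPM in DU145. Of 9 erythroid genes listed, 3 stand in the tables and 0 reached 1 CPM.

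Mitochondrially encoded messages made up 4.15%, 5.73%, 4.48% and 4.62% of the counts in DU145 and 6.59%, 3.80%, 6.41% and 4.76% in PC3, in the order circ0003553 control, circ0003553, circ0004592 control and circ0004592. Mitochondrial ribosomal RNAs made up 0.653%, 0.611%, 0.619% and 0.698% in DU145 and 1.17%, 0.983%, 1.14% and 1.14% in PC3.

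SNHG8, a small nucleolar RNA host gene, was lower in both lines with both circRNAs, as values only. It had 22.2 and 14.0 CPM in DU145 and 42.0 and 26.7 CPM in PC3 (control and circ0003553), and 20.8 and 12.7 CPM and 43.3 and 28.5 CPM (control and circ0004592). The paralemmin gene PALM3, given for circ0003553 alone, had 6.47 and 3.65 CPM and 45.7 and 27.6 CPM in DU145 and PC3, control first.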
